A study of Mus musculus with 12 samples.

How the data were processed

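RNA was sequenced from 12 libraries of mouse fibroblast lines. NIH-3T3 is an embryonic line and MLg a line from newborn lung. Each line received the amino-terminal fragment of Sonic hedgehog (SHHN) or vehicle for 48 h in low serum, and each of the 4 groups has 3 replicates. The labels do not say whether the replicates of a group were separate cultures, so every p-value here measures only the spread between these samples.

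The values are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), which the authors computed and deposited as 1 value per gene and library. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned to mm10 with TopHat2 2.0.12 and quantified with Cufflinks 2.2.1. The annotation behind the table and any scaling between libraries were not stated in the labels. The table gave 24346 genes with values, and 1 entry without values was left out. No symbol occurred more than once, and 95.7% of symbols were found in the GENCODE M21 annotation. Library columns were matched to samples by line, treatment and replicate number.

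Read counts were not used here, so the depth of each library is unknown and no counting interval or detection floor is given. FPKM totals over all genes ranged from 470218 to 659862 per library, but these totals do not measure depth. A search for values that are whole multiples of a smallest step, with a tolerance of 0.1, found 19.4% to 32.9% of low values per library, where arbitrary values give 20%, so counts could not be recovered.

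Genes with at least 0.5 FPKM in at least 3 of the 12 libraries were tested, which left 12379 genes. Values were analysed as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with 4 group means in 1 fit and a variance trend. Fold changes on this scale understate the change of genes with low values. The contrasts were SHHN against control in each line, the difference between these effects (NIH-3T3 minus MLg), and NIH-3T3 control against MLg control. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested in each contrast, with a threshold of 0.05, and an adjusted p is from limma unless camera is named. Errors of fold changes are standard errors (SE) of the fit, and errors of FPKM are standard deviations (SD) over the 3 libraries of a group.

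Gene lists with at least 5 tested members were compared with the other genes by camera in limma, with the correlation between genes preset at 0.01 and adjustment over the 24 lists of a contrast. The test was repeated with an estimated correlation. Members past the threshold were counted with adjustment over all genes and with adjustment over the list alone. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, for each SHHN comparison, the 12 genes with the highest and the 12 with the lowest fold change among those past the threshold with at least 1 FPKM and no overlap between treated and control libraries. It named the 6 highest and 6 lowest differences between lines, the 12 highest and 12 lowest genes of the control comparison with at least 10 FPKM, all Hedgehog genes of a fixed list, and the 4 members of each list with the smallest p. Predicted genes without a name were left out, and some genes that the rule names are not reported here. Members of a list that are named because they go against its direction, and genes in the other observations, were chosen after their values were seen.

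Replicate numbers were checked as possible pairs. After removal of group means, MLg control and treated libraries with the same number correlated across genes at 0.13, 0.16 and 0.24, above every pair with unequal numbers, so a fit with the replicate number as a block was read beside the MLg results. These correlations are across genes, which are not independent replicates.

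The alternatives were pseudocounts of 0.1 and 1, a filter of 1 FPKM, no filter, quantile normalization, median-ratio scaling, 6 libraries per fit, the replicate block, robust variance estimates, a required 2-fold change, the estimated correlation and leaving out each library in turn. Added after the data were seen were a correction for transcript length and GC content, alone and with the block, sums of near-identical gene copies, and a fit without both NIH-3T3 libraries numbered 2. Length and GC content were matched for 96.2% of the tested genes.

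Other splits of the samples and regroupings of residuals were refitted in the same way. The residual test drew its regroupings at random with a fixed seed. A further residual test, added after the results were seen, kept libraries of the same line and number together, regrouped these 6 pairs and exchanged control and treated within a pair at random, without and with the replicate block. In the first residual test, with the libraries in another order, the same seed drew other regroupings, whose highest count was lower, and the real count was the highest in either draw. The value printed is from the order that does not depend on computer settings.

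The procedure was tested on simulated data with the real control means of each line and the real spreads of 12379 genes. At each fold 100 genes were changed, in the same way in both lines. Of the genes changed 2-fold, 81% were recovered in the NIH-3T3 comparison and 80% in the MLg comparison. Of those changed 1.5-fold, 41% and 26% were recovered. There were 2 and 8 false calls, and 0 for the difference between lines. A shifted list was called, and 0 of the other lists were. The simulated noise was independent between genes and between libraries. So these counts do not cover correlated genes or the resemblance of MLg libraries with the same number. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.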

Results

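Gene expression was measured by RNA sequencing in 2 mouse fibroblast lines given recombinant SHHN, a secreted ligand of the Hedgehog pathway, or vehicle for 48 h. NIH-3T3 is a line from mouse embryos and MLg a line from newborn mouse lung. The 4 groups were NIH-3T3 control, NIH-3T3 SHHN, MLg control and MLg SHHN, with 3 libraries each. Values are FPKM as deposited, for 24346 genes, of which 12379 passed the filter on low values. Between 13401 genes (NIH-3T3 control replicate 2) and 14793 genes (MLg SHHN replicate 3) were above 0 per library. Spearman correlations across genes, which are not independent replicates, were 0.969 to 0.977 between replicates and 0.928 to 0.968 between libraries of unlike groups. The 20 most abundant genes held 16.0% ± 1.2 (SD, n = 3) of all FPKM in NIH-3T3 control and 13.1% ± 0.9 in NIH-3T3 SHHN. The sequencing depth is unknown.

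The question of the first comparison was which genes respond to SHHN in embryonic fibroblasts. Gli1, the transcription factor induced by the pathway, rose from 0.131 ± 0.0478 FPKM to 147 ± 6.69 FPKM (SD, n = 3), a log2 fold change of 7.87 (SE 0.15, adjusted p = 1.03e-12). Ptch1, the receptor of the ligand, rose from 2.39 ± 0.227 to 138 ± 23.2 FPKM (log2 fold change 5.57, SE 0.16). In mm10, Gli1 lies at chromosome 10:127329882-127341974 and Ptch1 at 13:63508328-63573598. Hes1, a repressor known as a Notch target, rose from 0.266 ± 0.285 to 51.0 ± 14.4 FPKM (6.10, SE 0.25), and Ctgf, a secreted matricellular protein, from 0.738 ± 0.147 to 36.1 ± 15.8 FPKM (4.81, SE 0.28). Further high rises were those of Syt13, a synaptotagmin (4.67, SE 0.18), Pgf, a growth factor of the VEGF family (4.68, SE 0.27), Hsd11b1, which reactivates glucocorticoids (3.98, SE 0.21), Sertad4 (3.97, SE 0.12) and Fam101a (3.95, SE 0.25). Lypd2 was listed at 0 in all NIH-3T3 control libraries and reached 12.8 ± 3.09 FPKM. 

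Among genes that fell in NIH-3T3, complement C3 went from 45.5 ± 8.03 to 1.47 ± 0.718 FPKM (log2 fold change −4.60, SE 0.29, adjusted p = 5.29e-08). The chemokines Ccl7 (−4.24, SE 0.22), Ccl5 (−3.77, SE 0.41) and Ccl2 (−3.70, SE 0.23) fell, as did Il1rl1, the receptor of interleukin 33 (−4.07, SE 0.30), the NF-kB cofactor Bcl3 (−3.87, SE 0.16) and the receptor Tlr2 (−3.50, SE 0.17). Sfrp2, a secreted Wnt modulator, fell from 286 ± 38.1 to 14.7 ± 4.96 FPKM (−4.29, SE 0.21). Prl2c2 (−4.50) and Prl2c3 (−3.96) also fell, but these are close copies of each other and their single values are uncertain. The pseudogene Rpl34-ps1 rose by 6.48 (SE 1.92, adjusted p = 0.0201), a call that ended without NIH-3T3 SHHN replicate 1 (0.0709) or 2 (0.0521) and without NIH-3T3 control replicate 1 (0.0691) or 3 (0.0792), and with no filter (0.0518) or robust variances (0.0783). Its values were 6.70 ± 11.6 FPKM in control and 187 ± 138 FPKM with SHHN. They are uncertain, and reads shared with other copies were not tested for it. Across all 12379 genes, limma called 2059 higher and 1826 lower, 31.4% together, and 808 and 442 of these changed at least 2-fold. With the 6 NIH-3T3 libraries alone in the fit, 1552 were higher and 1182 lower, and a fit of the 6 MLg libraries alone called 1740 and 1413. Which line had more calls thus depended on the spread shared across the 12 libraries. The balance of directions in NIH-3T3 depended on scaling, with 1958 higher and 2136 lower after quantile normalization, 2387 and 2628 with length and GC content corrected, and 2351 and 2500 with that correction and the replicate block.

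**Figure D1:**
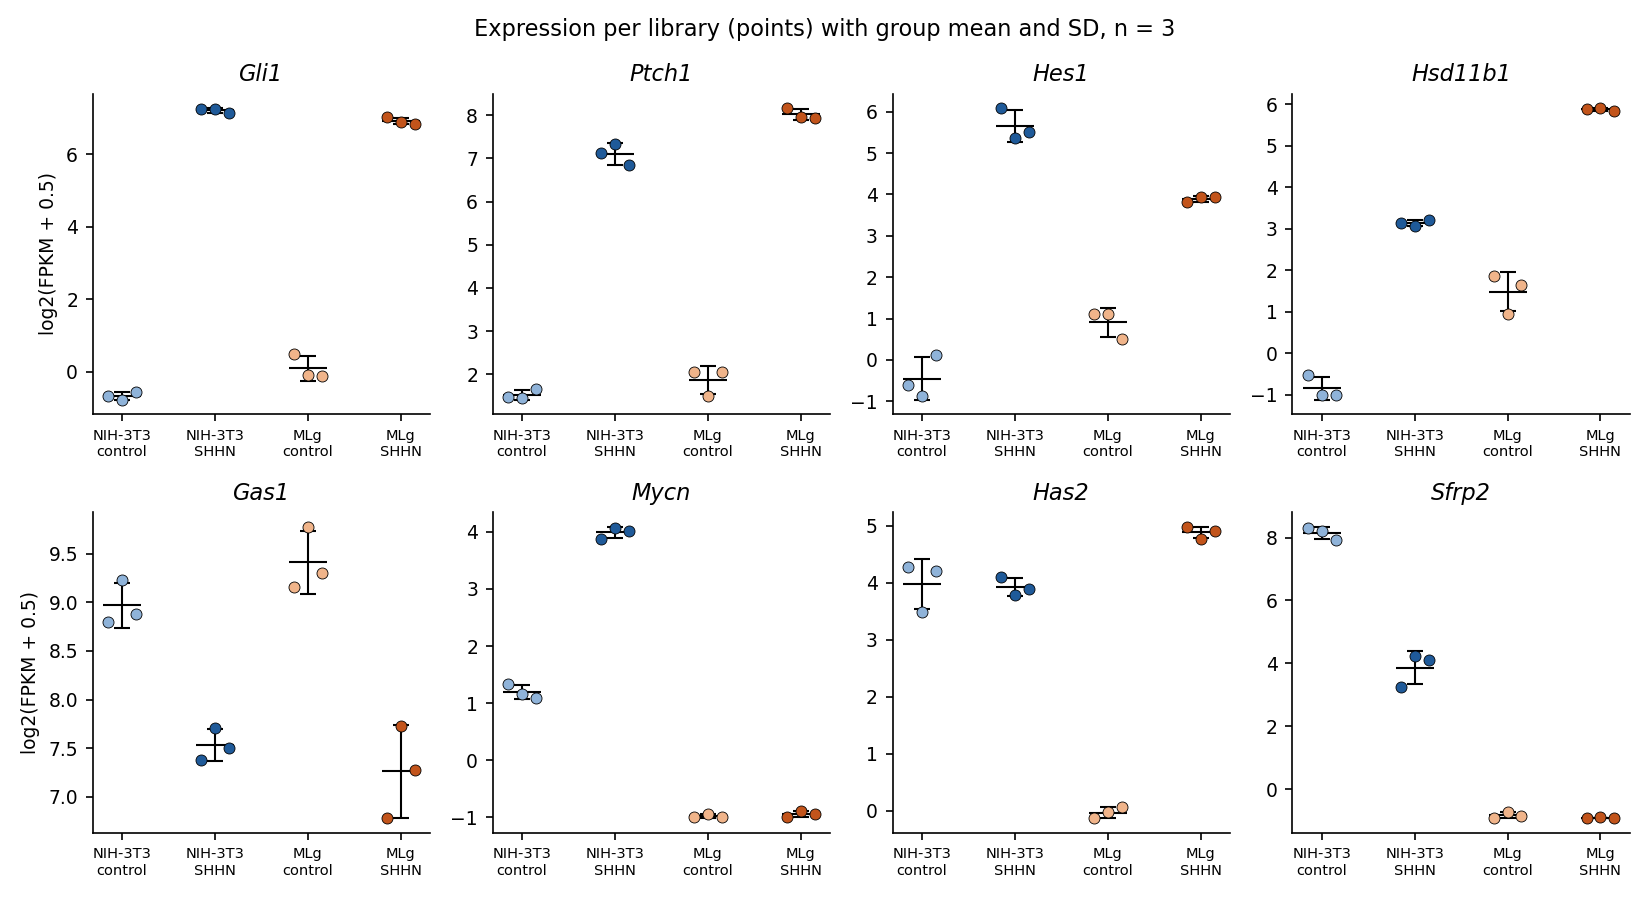
Expression of 8 genes in each library as log2(FPKM + 0.5), by group; points are libraries, the horizontal bar is the group mean and the error bar the SD (n = 3). Gli1 rose by a log2 fold change of 7.87 in NIH-3T3 and 6.83 in MLg, Mycn by 2.80 in NIH-3T3, and Has2 by 4.92 in MLg.

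Proliferation genes rose as a block in NIH-3T3. All 25 tested genes of the G2/M list rose, and all 25 adjusted over the list alone, with a median log2 fold change of 2.86 (camera adjusted p = 1.25e-27). Among them were the mitotic kinases Plk1 (3.19, SE 0.16) and Aurkb (3.12, SE 0.15), and Nusap1 (3.26, SE 0.21). All 26 tested genes of the G1/S and DNA replication list rose, and all 26 adjusted over the list alone (median 1.80, camera adjusted p = 2.5e-24), with Tk1 at 3.05, Rrm2 at 2.91 and the helicase subunit Mcm5 at 2.75 (SE 0.14). Of 19 tested Hedgehog target genes, 12 rose and 4 fell, the same counts adjusted over the list alone (median 1.60, camera adjusted p = 1.22e-05). 

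Lists of inflammation, matrix turnover and contraction moved down in NIH-3T3. Of 21 inflammatory cytokines and NF-kB targets, 15 fell and 0 rose, or 16 and 0 adjusted over the list alone (median −1.46, camera adjusted p = 2.07e-11). Of 23 interferon-stimulated genes, 11 fell, or 13 adjusted over the list alone (median −0.47, camera adjusted p = 3.15e-04), among them Ifi44 (−2.59). Matrix proteases and inhibitors had 10 of 23 lower, or 11 adjusted over the list alone (median −0.44, camera adjusted p = 1.11e-04), with Mmp9 at −2.27 (SE 0.21) and Mmp19 at −2.02 (SE 0.11), while Plaur rose by 0.66. These lists, G2/M, G1/S and the Hedgehog targets held with an estimated correlation, at adjusted p of 0.0177 to 0.0347. Of 20 contractile and myofibroblast genes, 12 fell and 2 rose, the same counts adjusted over the list alone (median −0.58, camera adjusted p = 0.00116, adjusted p = 0.109 with an estimated correlation). Lmod1 fell by a log2 fold change of 2.24 and Tagln went from 33.2 to 9.56 FPKM, while Ctgf and Thy1 (0.61) went against the list. 

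Weaker list calls in NIH-3T3 were lost with an estimated correlation. The p53 targets had 7 higher and 1 lower of 18, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0142, adjusted p = 0.105 with an estimated correlation), with Plk3 at 2.59 and Cdkn1a past no threshold (−0.11). Hypoxia and glycolysis genes had 12 higher and 3 lower of 20, or 13 and 3 adjusted over the list alone (0.0219, adjusted p = 0.296 with an estimated correlation). Hk2 rose by 1.41 while Adm (−2.59) and Ndrg1 (−1.35) fell, and the camera call ended without NIH-3T3 control replicate 3 (0.052) or SHHN replicate 1 (0.0767). Primary cilium genes had 10 lower and 2 higher of 32, the same counts adjusted over the list alone (0.0455, adjusted p = 0.419 with an estimated correlation). That call ended without NIH-3T3 control replicate 1 (0.0588) or 3 (0.0722), without SHHN replicate 1 (0.0767) and with length and GC content corrected (0.0889). Collagens and matrix assembly genes were not called as a list (0.139; 0.0435 without NIH-3T3 SHHN replicate 1), yet Col12a1 fell by a log2 fold change of 3.27 and the crosslinking enzyme Lox by 2.59.

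The MLg comparison asked the same of lung fibroblasts. Gli1 rose from 0.583 ± 0.280 to 120 ± 7.69 FPKM (SD, n = 3), a log2 fold change of 6.83 (SE 0.15, adjusted p = 1.13e-11). Ptch1 rose from 3.21 ± 0.772 to 260 ± 22.7 FPKM (6.15, SE 0.16). Has2, a hyaluronan synthase, rose from 0.476 ± 0.0643 to 29.0 ± 2.08 FPKM (4.92, SE 0.18). Ngfr, the neurotrophin receptor, rose from 0.150 to 16.4 ± 2.35 FPKM (4.71, SE 0.19), Sox18, a factor best known from endothelium, to 11.1 ± 0.763 FPKM (4.44, SE 0.15), and Hsd11b1 from 2.40 to 58.5 ± 1.25 FPKM (4.39, SE 0.21). Wfdc1 was listed at 0 in all MLg control libraries and reached 15.1 ± 0.783 FPKM. Sprr3 (4.36, SE 0.18), Steap4 (4.33, SE 0.43), Ctgf (3.66, SE 0.28) and Hes1 (2.98, SE 0.25) rose as well. 

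Among genes that fell in MLg, Il1rn, the natural antagonist of the interleukin 1 receptor, went from 66.7 ± 5.92 to 8.40 ± 0.565 FPKM (−2.92, SE 0.12, adjusted p = 3.76e-09). The chemokine Ccl8 (−3.10, SE 0.58), the lipase inhibitor Angptl4 (−2.93, SE 0.65), the protease Mmp3 (−2.86, SE 0.23), Ptgds (−2.78, SE 0.42) and Il1rl1 (−2.75, SE 0.30) fell. So did the metallothionein Mt2, from 323 ± 17.3 to 60.6 ± 24.9 FPKM (−2.50, SE 0.35), and Cemip, which takes part in hyaluronan breakdown, from 114 ± 22.2 to 20.1 ± 3.82 FPKM (−2.48, SE 0.20). Across genes, limma called 1580 higher and 1238 lower, 22.8% together, of which 650 and 317 changed at least 2-fold. The count of lower genes was 815 without MLg SHHN replicate 3. The balance of directions turned here too, with 1476 higher and 1588 lower after quantile normalization, 1895 and 1955 with length and GC content corrected, and 1860 and 1882 with that correction and the replicate block.

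Cell cycle genes rose in MLg too. All 26 G1/S and DNA replication genes rose (median 1.96, camera adjusted p = 1.12e-30), with Mcm5 at 2.36 and the cyclin Ccne1 at 2.18, and so did all 25 G2/M genes (median 2.04, camera adjusted p = 9.5e-28), with Top2a at 3.14. Both counts were the same adjusted over the list alone. Interferon-stimulated genes fell in 18 of 23, also 18 adjusted over the list alone (median −0.85, camera adjusted p = 5.94e-10), with Ifit1 at −1.68, Ifit3 at −1.53 and Isg15 at −1.48. Inflammatory genes had 11 lower and 1 higher of 21, or 11 and 2 adjusted over the list alone (median −0.78, camera adjusted p = 2.72e-06). Cxcl1 (−1.90) and Cxcl12 (−1.42) fell, and Ptges went the other way (0.41). These lists held with an estimated correlation, at adjusted p of 0.0109 to 0.0333.

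Other list calls in MLg did not hold with an estimated correlation. Cholesterol synthesis genes had 13 higher and 0 lower of 23, or 17 and 0 adjusted over the list alone (median 0.65, camera adjusted p = 3.13e-06, adjusted p = 0.344 with an estimated correlation), among them Lss (1.06) and Idi1 (1.01). Hox genes had 13 lower and 0 higher of 27, the same adjusted over the list alone (median −0.45, camera adjusted p = 1.04e-05, adjusted p = 0.123 with an estimated correlation), with Hoxb8 at −1.16. Of the Hedgehog targets 9 rose and 3 fell of 19, or 9 and 4 adjusted over the list alone (median 0.26, mean 1.43, camera adjusted p = 0.00115, adjusted p = 0.119 with an estimated correlation). Matrix proteases and inhibitors had 10 lower and 3 higher of 23, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.00819, adjusted p = 0.0513 with an estimated correlation), with the inhibitors Timp3 (1.96) and Timp4 (1.65) and the receptor Plaur (0.72) going up. Lung mesenchyme transcription factors had 11 lower and 4 higher of 20, or 12 and 4 adjusted over the list alone (0.0161, adjusted p = 0.306 with an estimated correlation), with Meis1 (−1.51) and Tbx5 (−1.03) down and Twist2 (1.83), Snai1 (1.70) and Nr2f2 (1.55) up. 

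The last MLg list calls were close to the threshold. ER stress genes had 4 lower and 1 higher of 23, the same adjusted over the list alone (0.031, adjusted p = 0.471 with an estimated correlation), a call that ended without MLg control replicate 2 (0.121), without MLg SHHN replicate 2 (0.0689), with quantile normalization (0.0881) and with length and GC content corrected (0.0755, and 0.08 with the block). TGF-beta and BMP response genes had 9 lower and 4 higher of 22, or 10 and 5 adjusted over the list alone (0.0478, adjusted p = 0.231 with an estimated correlation). With the replicate block its adjusted p was 0.0612, so the list call is not counted as holding. Within it, Grem1, a BMP antagonist, fell from 149 to 26.0 FPKM (−2.46, SE 0.18) and Id3 from 40.5 to 7.60 FPKM (−2.32, SE 0.29), while Inhba rose by 1.22. Contractile genes were not called (0.096; 0.0492 without MLg SHHN replicate 1 and 0.0485 without MLg control replicate 1), nor were endothelial markers (0.156; 0.0484 without NIH-3T3 SHHN replicate 1 and 0.0235 with a filter of 1 FPKM).

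Several Hedgehog genes changed in the same direction in both lines, though not all by the same amount. Bcl2, a survival factor, rose by 1.60 in NIH-3T3 and 1.67 in MLg (SE 0.13 each). The transcription factor Gli2 rose by 2.63 and 1.26 (SE 0.14 each), with a difference between the lines of 1.38 (adjusted p = 5.32e-04). Rasl11b rose by 3.30 and 2.31 (difference 0.99, adjusted p = 0.0347, a call lost under several alternatives, such as 0.0643 with no filter and 0.0811 without MLg SHHN replicate 1). Foxl1 rose by 1.64 and 0.89, and its difference did not pass (0.74, adjusted p = 0.102) except with a pseudocount of 1 (0.0267) or without NIH-3T3 control replicate 1 (0.0269). Gas1, a surface protein that binds the ligand, fell from 505 ± 82.6 to 185 ± 21.5 FPKM in NIH-3T3 (−1.44, SE 0.22) and from 692 ± 163 to 159 ± 51.3 FPKM in MLg (−2.15, SE 0.22). The difference of 0.71 for Gas1 did not pass (adjusted p = 0.162), but passed with the replicate block (0.023, and 0.0355 with length and GC content corrected as well) and with quantile normalization (0.0348). Osr1 fell by 2.31 and 1.10 (SE 0.18 each, difference −1.21, adjusted p = 0.00773). Foxc2 rose by 1.73 in NIH-3T3. Its rise of 0.66 in MLg (adjusted p = 0.0297) did not pass without MLg SHHN replicate 2 (0.137) or 3 (0.109), without MLg control replicate 1 (0.0613), 2 (0.0534) or 3 (0.0914), with no filter (0.0565), with quantile normalization (0.0528) or with 6 libraries per fit (0.0557). Bmp4, near 0 in NIH-3T3, fell in MLg from 30.2 ± 3.24 to 11.5 ± 0.184 FPKM (−1.35, SE 0.13). Hhip was too low to be tested.

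Small changes of some Hedgehog genes depended on single libraries or settings. The changes given for Ccnd2, Gli3, Cdon, Foxf2 and Foxf1 were those in NIH-3T3, and none of these genes passed in MLg. Ccnd2 fell by 0.70 (adjusted p = 0.00461; 0.0516 with 6 libraries per fit), Gli3 by 0.70 (0.0166; 0.0637 without NIH-3T3 SHHN replicate 3, 0.0661 without control replicate 1, 0.0742 without control replicate 3, 0.0906 with 6 libraries per fit) and Cdon by 0.61 (0.0171; 0.0746 without SHHN replicate 1, 0.0541 without control replicate 1, 0.0786 without control replicate 3, 0.0684 with 6 libraries per fit). Foxf2 rose by 0.72 (0.0266; 0.123 without SHHN replicate 1, 0.0534 without control replicate 1, 0.086 without control replicate 3, 0.0527 with no filter, 0.0658 with 6 libraries per fit, 0.0573 with length and GC content corrected). Foxf1 (−0.42, 0.0418) lost its call without NIH-3T3 SHHN replicate 1 (0.123) or 3 (0.101), NIH-3T3 control replicate 1 (0.126) or 3 (0.0834), MLg SHHN replicate 3 (0.0601) or MLg control replicate 1 (0.0542), and with a pseudocount of 1 (0.0553), no filter (0.0562) or 6 libraries per fit (0.0849). Sfrp1 in MLg (−0.86, 0.0461) lost its call without any of the 6 MLg libraries (0.0683 to 0.135), without NIH-3T3 control replicate 1 (0.0537) or 3 (0.0547) and with no filter (0.0934). In NIH-3T3 it did not pass (−0.01), but rose by 0.46 without NIH-3T3 SHHN replicate 1 (0.0293). Boc did not pass in NIH-3T3 (−0.28, 0.135; 0.0141 with length and GC content corrected).

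The lines were compared gene by gene to ask how far the responses are shared. Both lines called 914 genes higher, where independent lists would share 262.8 (odds ratio 11.6), and 519 genes lower, where independent lists would share 183 (odds ratio 5.43). Gli1, Ptch1, Hes1, Ctgf, Hsd11b1 and Sox18 were among the shared rises, and Il1rl1, Cemip, Mt2 and Gas1 among the shared falls. The shared rises made up 44.4% of those in NIH-3T3 and 57.8% of those in MLg. Opposite calls numbered 66 genes higher in NIH-3T3 and lower in MLg and 48 the other way. Fold changes correlated across all tested genes with Pearson 0.549 and Spearman 0.413, and with Pearson 0.598 over the 5156 genes called in either line. Genes are not independent replicates.

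**Figure D2:**
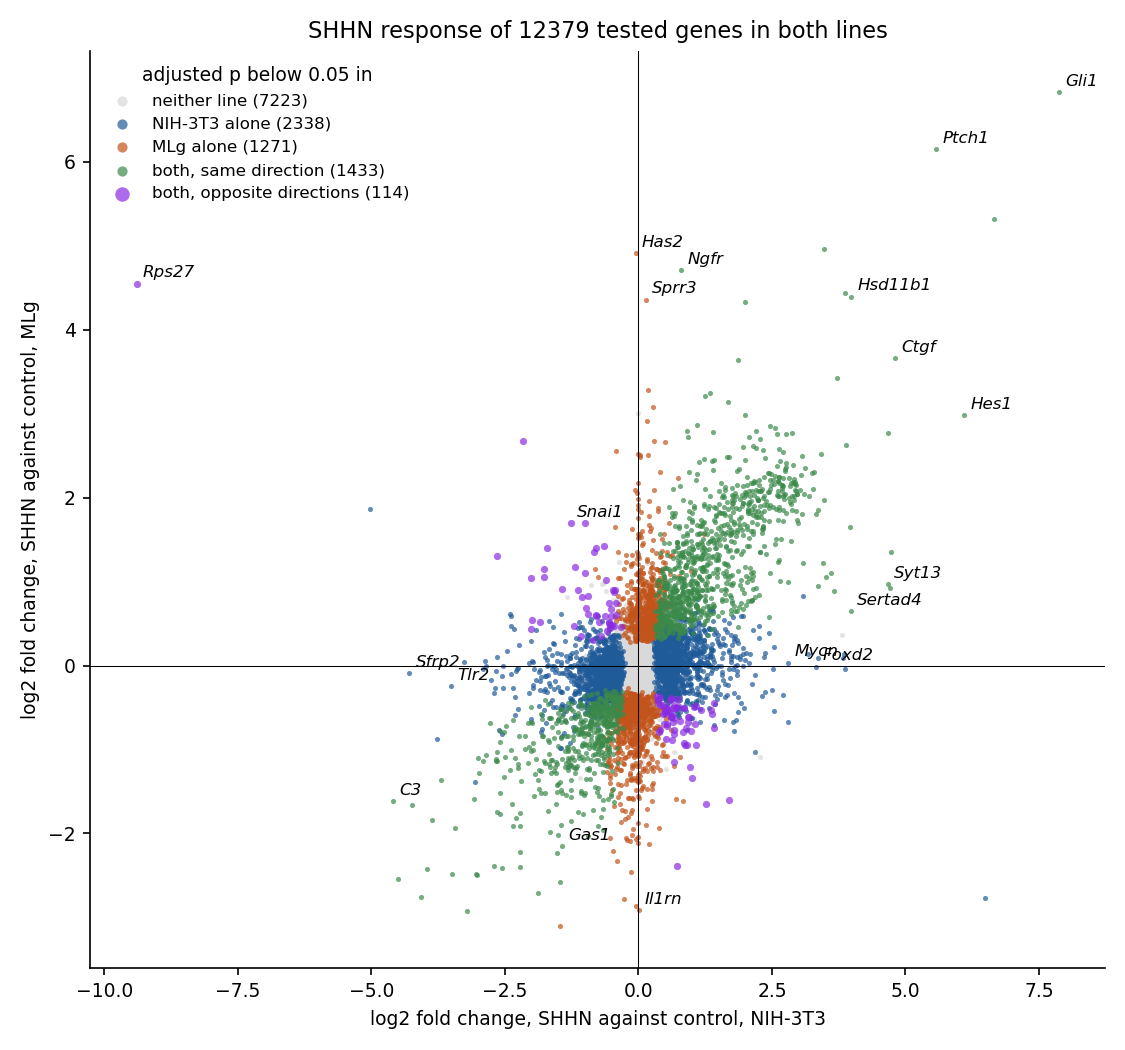
Log2 fold change by SHHN in NIH-3T3 (x axis) and MLg (y axis) for the 12379 tested genes; colours give the line or lines in which adjusted p was below 0.05. Gli1 and Ptch1 lie far out in both lines, Has2 and Sprr3 in MLg alone, Foxd2 and Mycn in NIH-3T3 alone, and Rps27 shares its sequence with a copy.

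Differences between the responses were tested directly. Has2 did not pass in NIH-3T3 (15.7 ± 4.46 FPKM in control and 14.7 ± 1.67 with SHHN, log2 fold change −0.05), and its effect differed from that in MLg by −4.97 (SE 0.26, adjusted p = 1.34e-07). Sfrp2 (−4.20, SE 0.30) and Tlr2 (−3.26, SE 0.24) responded more strongly downward in NIH-3T3, but both had means below 0.2 FPKM in both MLg groups. The forkhead gene Foxd2 rose from 5.58 to 59.8 FPKM in NIH-3T3 and did not pass in MLg (−0.01, difference 3.34, SE 0.36, adjusted p = 5.23e-05), and its relative Foxd1 rose from 29.9 ± 9.18 to 182 ± 84.0 FPKM in MLg and had a mean under 0.1 FPKM in both NIH-3T3 groups (difference −2.47, SE 0.42). Mycn, a growth-promoting transcription factor, rose from 1.79 to 15.4 FPKM in NIH-3T3 and stayed near 0 in MLg (difference 2.77, SE 0.18). Cyclin D1 (Ccnd1) rose by 1.59 in NIH-3T3, and the difference from MLg was 1.33 (SE 0.22, adjusted p = 0.00119). Smo, the signal transducer of the pathway, rose from 122 to 292 FPKM in NIH-3T3 (difference 1.44, SE 0.24). Further differences were those of Tspan33 (3.91), Lypd2 (3.79), Ucma (3.74), Lrrc8d (3.71), Syt13 (3.70) and Sprr3 (−4.22). Tspan33, Lypd2, Ucma and Syt13 had means under 1 FPKM in both MLg groups, and Sprr3 in both NIH-3T3 groups. Snai1, a repressor of epithelial genes, fell in NIH-3T3 (−1.26) and rose in MLg (1.70), a difference of −2.96 (SE 0.24). In all, 926 differences were positive and 736 negative, 1662 together, with 1093 without MLg SHHN replicate 3 and 2499 with length and GC content corrected. The balance of directions turned here as well. Positive differences were 55.7% of the 1662, but 47% of 2345 without NIH-3T3 control replicate 2 and 48% of 1712 without both NIH-3T3 libraries numbered 2. Of the 1662 genes, 809 were called in NIH-3T3 alone, 427 in MLg alone, 253 in both in the same direction, 114 in opposite directions and 59 in neither.

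Among lists, the G2/M genes had a larger rise in NIH-3T3, with 13 of 25 positive and 1 negative difference, or 19 and 1 adjusted over the list alone (median 0.78, camera adjusted p = 1.64e-07, adjusted p = 0.259 with an estimated correlation). Cdc20 differed by 1.30 and Aurka by 1.26, and Top2a by −1.46. The G1/S list was not called (median −0.08, camera adjusted p = 0.855). Inflammatory genes fell further in NIH-3T3 (8 negative and 1 positive of 21, or 9 and 2 adjusted over the list alone, 4.76e-04, adjusted p = 0.195 with an estimated correlation). Cholesterol synthesis (0 positive and 3 negative of 23, or 0 and 11 adjusted over the list alone) had 4.76e-04, adjusted p = 0.492 with an estimated correlation. Hox genes (8 positive of 27, or 11 adjusted over the list alone) had 8.81e-04, adjusted p = 0.259 with an estimated correlation. For hypoxia genes (6 positive and 1 negative of 20, or 9 and 1 adjusted over the list alone) the values were 9.13e-04 and adjusted p = 0.259 with an estimated correlation. TGF-beta and BMP response genes (8 positive and 1 negative of 22, the same adjusted over the list alone) had 0.00183, adjusted p = 0.195 with an estimated correlation. No list difference held with an estimated correlation.

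A pair of list differences was weaker still. The Hedgehog targets (8 positive and 3 negative of 19, or 9 and 4 adjusted over the list alone, median 0.74) had 0.0331, adjusted p = 0.259 with an estimated correlation, and 0.0691 with the replicate block, 0.065 without MLg control replicate 1, 0.0689 without NIH-3T3 control replicate 2, 0.0847 with quantile normalization and 0.0562 with length and GC content corrected. The pericyte markers (3 negative of 5, the same adjusted over the list alone, median −1.05) had 0.0335, adjusted p = 0.259 with an estimated correlation, and 0.0513 with the block, 0.0545 without MLg SHHN replicate 1, 0.0542 without MLg control replicate 1, 0.0943 without NIH-3T3 control replicate 1, 0.0689 without NIH-3T3 control replicate 2, 0.0503 with a pseudocount of 1 and 0.0501 with quantile normalization.

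**Figure D3:**
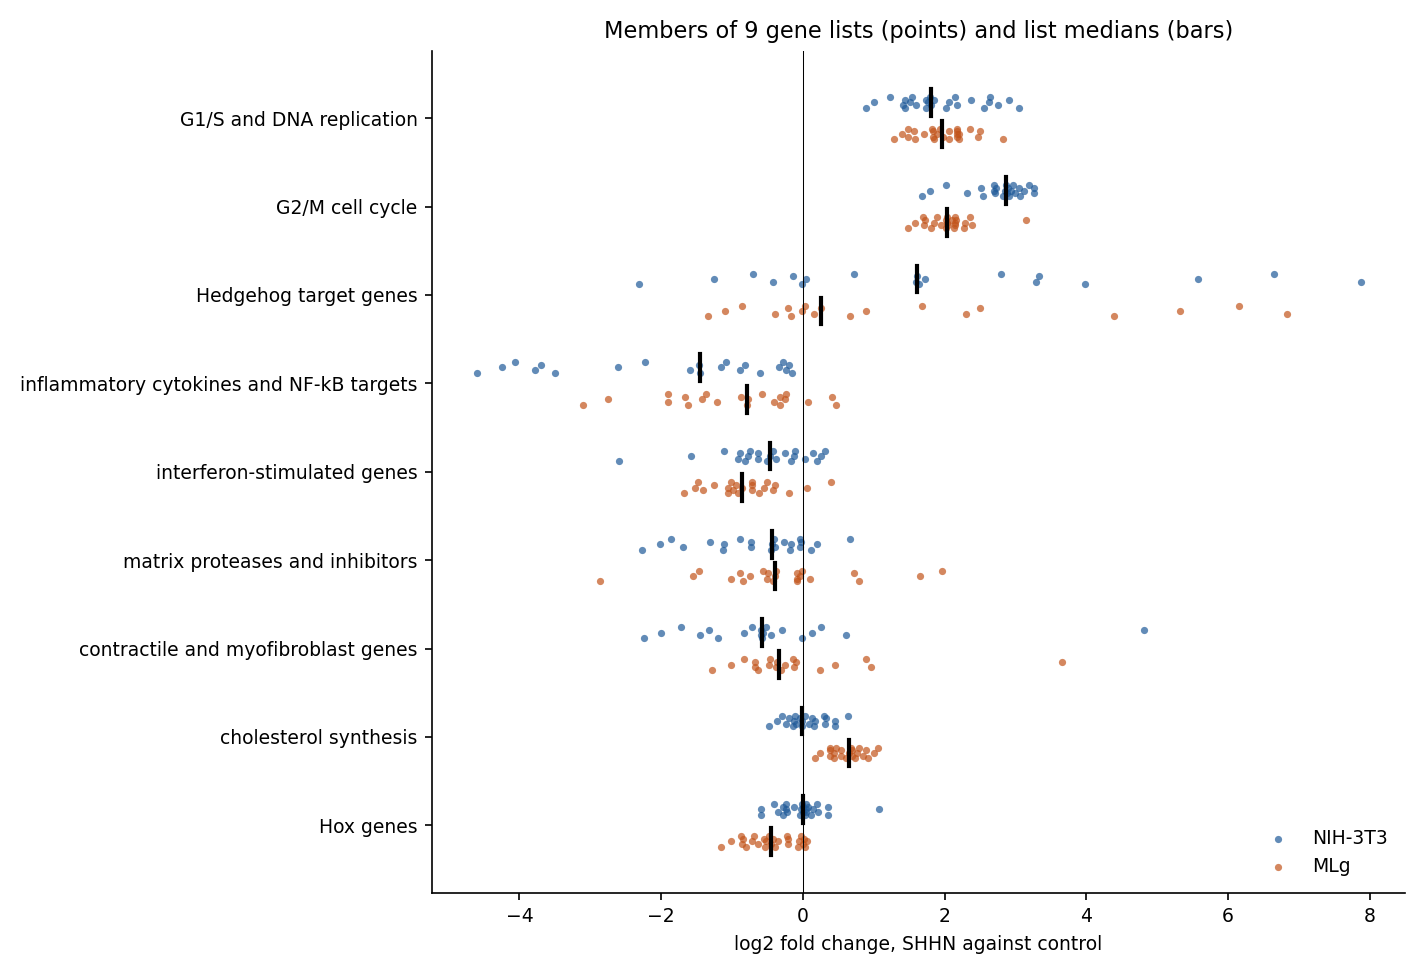
Log2 fold change by SHHN of the tested members of 9 gene lists in NIH-3T3 and MLg; points are genes and black bars list medians. The G2/M median was 2.86 in NIH-3T3 and 2.04 in MLg, and the medians of cholesterol synthesis and Hox genes in MLg were 0.65 and −0.45, with adjusted p = 0.344 and 0.123 with an estimated correlation.

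The ribosomal protein gene Rps27 had the largest fitted changes, −9.40 (SE 0.43) in NIH-3T3 and 4.55 (SE 0.43) in MLg, and it has a near-identical copy, Rps27rt. In NIH-3T3, Rps27 went from 4460 to 5.11 FPKM while Rps27rt went from 1667 to 5862 FPKM. The sum of both went from 6127 to 5867 FPKM, a log2 fold change of −0.07 (SE 0.22), and in MLg by −0.30 (SE 0.22). Amd1 alone changed by −5.03 in NIH-3T3, and its sum with Amd2 by 0.19 (SE 0.15). In MLg Amd1 alone did not pass (1.87, SE 1.15), and the sum rose by 0.76 (SE 0.15, adjusted p = 0.00186). Rnaset2a changed by −2.16 in NIH-3T3 and 2.67 in MLg, and its sum with Rnaset2b by −0.61 and 0.15 (SE 0.15 each). The single values of these genes are uncertain.

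**Figure D4:**
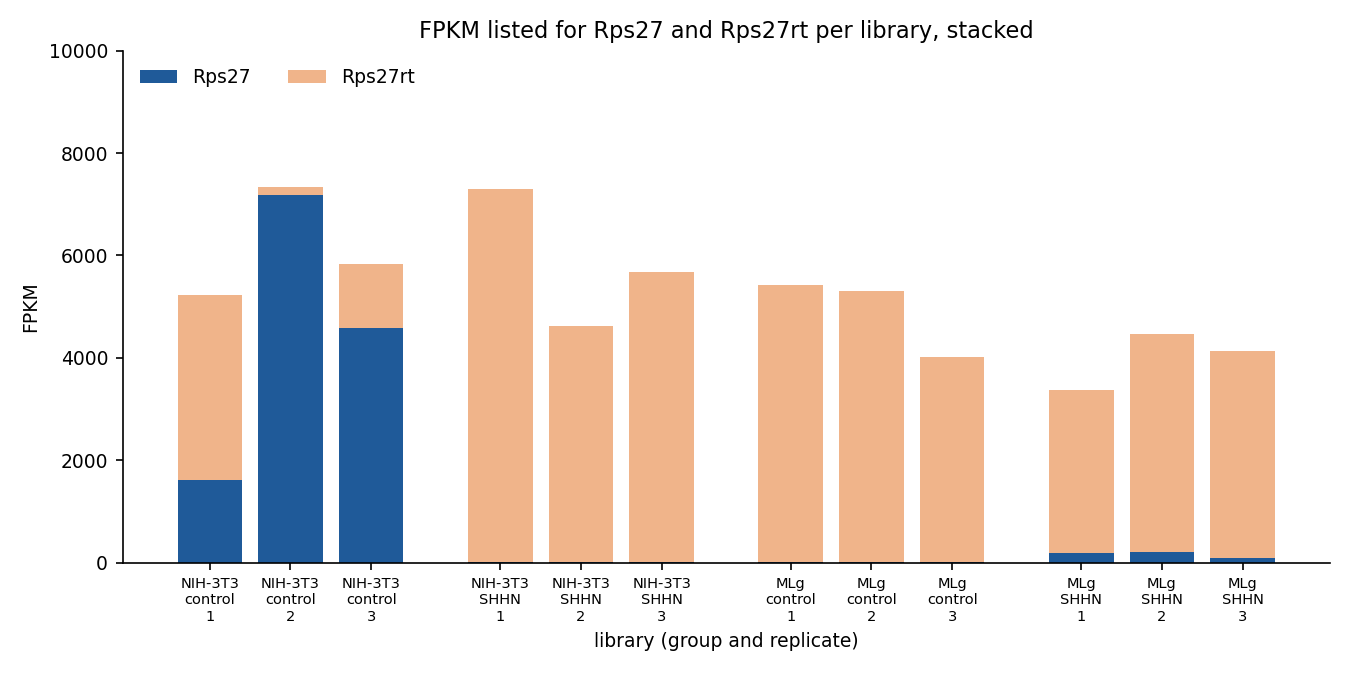
FPKM of Rps27 and Rps27rt in each of the 12 libraries, stacked, by group and replicate. Rps27 had most of the FPKM only in NIH-3T3 control replicates 2 and 3, and the group means of the sum were 6127, 5867, 4917 and 3993 FPKM from left to right.

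The control libraries showed how far the lines differ without the ligand. Dlk1, an imprinted membrane protein of fetal tissue, had 2318 ± 491 FPKM in NIH-3T3 and 0.890 ± 0.141 in MLg (SD, n = 3; log2 fold change 10.69, SE 0.20, adjusted p = 1.35e-13). The retinoic acid binding protein Crabp1 (9.69), the imprinted RNA Meg3 (9.55), the receptor Agtr2 (9.48), Sfrp2 (8.98), Efemp1 (8.56), Cd34 (8.03) and the fibroblast surface antigen Thy1 (7.74) were higher in NIH-3T3. Plac8 (−8.08), Grem1 (−7.95), the protease Htra1 (−7.51), Il1rn (−7.03), the imprinted gene Sgce (−6.72), the complement regulator Serping1 (−6.49) and the crosslinking enzyme Loxl2 (−6.21) were higher in MLg. Of 27 Hox genes, 18 were lower and 8 higher in NIH-3T3, the same adjusted over the list alone, with Hoxb9 at −6.05 and Hoxd8 at 5.75 (camera adjusted p = 9.34e-04, adjusted p = 0.515 with an estimated correlation). Interferon-stimulated genes were lower in NIH-3T3 in 16 of 23, or 17 adjusted over the list alone (7.96e-06, adjusted p = 0.0588 with an estimated correlation). G2/M genes were lower in 23 and higher in 1 of 25, the same adjusted over the list alone (1.24e-07, adjusted p = 0.515 with an estimated correlation), and G1/S genes lower in 19 and higher in 2 of 26, the same adjusted over the list alone (0.00282, adjusted p = 0.515 with an estimated correlation). Across genes, 3020 were higher and 3185 lower in NIH-3T3, 50.1% of those tested, and the balance turned with quantile normalization (3210 and 3171), without NIH-3T3 control replicate 2 (3247 and 3110) and without both NIH-3T3 libraries numbered 2 (3156 and 3034). Line, tissue and age of origin, mouse strain and growth serum before treatment differ together between these libraries.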

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

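The sums over near-identical gene copies, the correction for length and GC content and the regroupings by pairs were chosen after the data were seen, and the tests of library composition, low expression and other splits before their results were seen. A result is listed here because limma's test of the difference between the lines passed. It passed for 1662 genes, and regroupings of the residuals of a model without such differences called at most 1190 genes. The real count was as high in 1 of 100, itself, but these regroupings ignore that MLg libraries of the same number resemble each other. With the libraries of the same number kept together as pairs, 5 of 100 regroupings gave as many, the real one included, and the highest other called 2644. With the replicate block it was again 5 of 100, the real one with 1692 genes and the highest other with 2912. The residuals of that model keep any real difference between the lines. Random exchanges within pairs can rebuild the real contrast or its reverse, so this test could hardly give a share under 0.05. The regroupings by pairs therefore decide nothing, and chance is neither shown nor excluded for the count. Each value that follows is the log2 fold change in NIH-3T3 minus that in MLg.

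Differences above 0 were those of Tspan33 (3.91), Lypd2 (3.79), Ucma (3.74), Lrrc8d (3.71), Syt13 (3.7), Foxd2 (3.34), Sertad4 (3.33), Hes1 (3.12), Il1rn (2.92), Mmp3 (2.82), Mycn (2.77), Ptgds (2.51), Fam101a (2.3), Pgf (1.91), Smo (1.44), Gli2 (1.38), Ccnd1 (1.33), Bmp4 (1.2), Ctla2a (1.11), Gli1 (1.04), Foxc2 (1.06), Rasl11b (0.99) and the pseudogene Rpl34-ps1 (9.25). Differences below 0 were those of Spp1 (−0.85), Osr1 (−1.21), Wfdc1 (−1.48), Prl2c3 (−1.54), Prl2c2 (−1.95), Bcl3 (−2.03), Steap4 (−2.33), Ccl2 (−2.34), Foxd1 (−2.47), Ccl7 (−2.59), Ccl5 (−2.9), C3 (−2.99), Tlr2 (−3.26), Ngfr (−3.91), Sfrp2 (−4.2), Sprr3 (−4.22), Rnaset2a (−4.83), Has2 (−4.97), Amd1 (−6.89) and Rps27 (−13.95). The call of Foxc2 ended without MLg SHHN replicate 1, MLg control replicate 1 or 2, NIH-3T3 SHHN replicate 2 or NIH-3T3 control replicate 3 (adjusted p 0.0523 to 0.068), and with length and GC content corrected (0.0521, and 0.0697 with the block). That of Rasl11b ended without any of the 3 MLg SHHN libraries, MLg control replicate 1 or 2, NIH-3T3 SHHN replicate 2 or 3 or NIH-3T3 control replicate 1 (0.058 to 0.0811), without both NIH-3T3 libraries numbered 2 (0.0584) and with no filter (0.0643). Spp1 lost its call without MLg SHHN replicate 1 or 3, MLg control replicate 2 or 3 or NIH-3T3 SHHN replicate 2 or 3 (0.0543 to 0.0721), without both NIH-3T3 libraries numbered 2 (0.0801), with median-ratio scaling (0.053) and with length and GC content corrected (0.0888). Rpl34-ps1 lost its call without any of the 3 MLg control or 3 NIH-3T3 SHHN libraries or NIH-3T3 control replicate 1 or 3 (0.052 to 0.0949), with no filter (0.0878), with robust variances (0.124) and with a pseudocount of 0.1 (0.0517). Its values varied widely within groups (150 ± 164 FPKM in MLg SHHN), and reads shared with other copies were not tested for it. The call of Bmp4 ended with a pseudocount of 0.1 (0.138), and that of Amd1 with robust variances (0.0525). Il1rn, Mmp3, Ptgds and Bmp4 fell in MLg and had means under 1 FPKM in both NIH-3T3 groups, so NIH-3T3 could hardly show a fall. Sfrp2 and Tlr2 fell in NIH-3T3 and had such means in both MLg groups. Tspan33, Lypd2, Ucma, Syt13 and Mycn also had means under 1 FPKM in both MLg groups, and Foxd1, Ngfr and Sprr3 in both NIH-3T3 groups. For lists, the median difference was 0.74 for Hedgehog targets, 0.78 for G2/M, −0.57 for inflammatory genes, 0.67 for TGF-beta and BMP response, −0.62 for cholesterol synthesis, 0.39 for hypoxia, 0.43 for Hox genes and −1.05 for pericyte markers. None of these list calls held with an estimated correlation.

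Rps27, Amd1 and Rnaset2a had differences of −13.95, −6.89 and −4.83, each in a gene with a near-identical copy. Reads shared between copies are a candidate explanation, since the difference of the summed copies was 0.2238 (SE 0.306) for Rps27, −0.5736 (SE 0.211, adjusted p = 0.0928) for Amd1 and −0.754 (SE 0.208, adjusted p = 0.0289) for Rnaset2a. The remaining difference of Rnaset2a with its copy still passed the threshold. In NIH-3T3 the control libraries had 1619, 7184 and 4576 FPKM for Rps27, and the SHHN libraries 5.59, 4.20 and 5.54. For Amd1 the values were 13.7, 16.7 and 43.0 in control and 0.250, 0.0125 and 0.298 with SHHN. A strain variant would steer reads alike in all libraries of a line. So these values argue against it as the whole cause for Rps27 and Amd1, and for Rnaset2a it was not tested.

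The G2/M list rose in both lines, and the larger rise in NIH-3T3 passed camera with the preset correlation but not with an estimated correlation (adjusted p = 0.259). Transcript length and GC content are argued against as the whole cause of the rise within each line. The median after correction was 2.889 in NIH-3T3 (2.863 before) and, with the block, 1.984 in MLg (2.035 before). After quantile normalization the list medians were 2.712 and 1.993, and the all-gene medians −0.047 in NIH-3T3 and −0.0439 in MLg. So small a shift of all genes could hardly remove a rise of this size, so this test alone does not decide on library composition. A composition effect would scale all genes of a library together, yet before quantile normalization the all-gene medians were −0.0123 in NIH-3T3 and −0.00261 in MLg. Beside the list medians, these values argue against library composition as the whole cause of the rise within each line. All these medians are of the rise within a line, not of its difference between the lines. The labels give no sequencing batch, and a difference between the lines in growth state stays open. In the control libraries 23 of the 25 G2/M genes were lower in NIH-3T3 (median −1.22, adjusted p = 0.515 with an estimated correlation).

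Most of the genes that differed between the lines were called in 1 line alone, 809 in NIH-3T3 and 427 in MLg. A gene near 0 in a line cannot show a fall there, yet only 21.4% of the 1662 genes (356 genes, exact 95% interval 19.5% to 23.5%) had means under 1 FPKM in both groups of the line with the smaller change. The interval treats genes as independent draws, which they are not. The share is over all 1662 genes, also those called in both lines or in neither, and over rises as well as falls. Low expression is therefore argued against only as the whole cause for the 1662 genes together. It was not tested apart for the genes called in 1 line alone, and it stays open for those 356 genes. Differences between the lines in tissue and age of origin, strain and serum remain open and untested.

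Within a line the 6 libraries make 10 splits, too few for a share under 0.05. For SHHN in NIH-3T3 the real split called 2734 genes, the highest other 0, and 1 of the 10 splits gave as many. In MLg the real split called 3153 and the highest other 1, which parts 1 pair of replicate numbers, while the other splits that part all 3 pairs called 0. For the control libraries the values were 5160 and 1. For genes called in the same direction in both lines, 1 of 200 pairs of splits gave as many, the real one with 1254 genes and the highest other with 95. That other pair is the real splits with control and SHHN exchanged in 1 line. Splits other than the real ones called at most 1 gene within a line, which fixes this outcome, so the pairs decide no more than the 10 splits of each line.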

How the results depend on the processing

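The corrections for length and GC content, the summed copies and the fit without both NIH-3T3 libraries numbered 2 were chosen after the data were seen. Of 564 results for single genes, 453 kept their direction and side of the threshold under every alternative run, and of 72 list results 45 did. Requiring a 2-fold change, which by construction lowers counts, gave 808 higher and 442 lower in NIH-3T3, 650 and 317 in MLg, 1087 and 1324 between controls, 847 differences between lines and 542 shared genes. With 6 libraries per fit 1552 genes were higher and 1182 lower in NIH-3T3, and 1740 and 1413 in MLg, so MLg then had more calls than NIH-3T3. Correcting length and GC content gave 1955 lower genes in MLg and 2499 differences between lines, and 1882 lower genes in MLg with the block. The estimated correlation left 6 of 10 list calls in NIH-3T3, 4 of 11 in MLg and 0 of 8 for the difference. For these the cause was not tested. Leaving out each library in turn gave 1655 to 2148 higher and 1390 to 2127 lower genes in NIH-3T3, 1193 to 1808 and 815 to 1454 in MLg, 2593 to 3247 and 2731 to 3180 between controls, 1093 to 2345 differences, 1158 to 1527 shared genes, and 8 to 10, 9 to 12 and 6 to 11 list calls. Both 815 and 1093 were without MLg SHHN replicate 3. Signs reversed for Amd1 in NIH-3T3 (0.19), Rps27 in MLg (−0.30) and the Rps27 difference (0.22) when copies were summed, and for Sfrp1 in NIH-3T3 without NIH-3T3 SHHN replicate 1, the highest of its values from −0.291 to 0.461 with 1 library left out, where the cause was not tested.

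With the replicate block, 1598 genes were higher and 1232 lower in MLg, and no MLg call of a named gene or list changed but that of the TGF-beta and BMP list (0.0612). In NIH-3T3 libraries with the same number were no more alike than others (−0.0007, −0.10 and 0.027), so the block was read for MLg. No symbol was duplicated, so summing duplicates moved nothing. Depth is unknown, which leaves open how much of the spread at low FPKM is counting error.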

Other observations

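The lists for YAP/TEAD, Notch and growth arrest were tested after the rises of Ctgf and Hes1 and the fall of Gas1 had been seen, and the genes in the last paragraph were chosen after their values were seen. Ctgf, a target of YAP and TEAD, rose in both lines, but the other 19 tested members of a YAP/TEAD list had a median log2 fold change of 0.0677 in NIH-3T3 (6 higher, 4 lower) and −0.249 in MLg (1 higher, 7 lower; camera adjusted p = 4.86e-04 downward, adjusted p = 0.165 with an estimated correlation). Cyr61, another such target, fell by 1.27 in NIH-3T3 and 1.85 in MLg. For Hes1, the other 10 tested Notch genes had medians of 0.126 and −0.289, with 3 higher and 0 lower in NIH-3T3 and 1 higher and 3 lower in MLg. For Gas1, the other 19 growth arrest genes had medians of 0.0124 and −0.1, with 5 higher and 4 lower in NIH-3T3 and 1 higher and 6 lower in MLg. Among the Notch genes, the ligand Jag1 rose by 1.66 in NIH-3T3 and 2.49 in MLg. Called members went both ways in each list and line, except for the Notch genes in NIH-3T3. The Notch list also holds ligands and receptors beside targets. So these medians do not decide whether YAP/TEAD or Notch activity or release from growth arrest may have a part in the change of each gene.

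Some imprinted genes and genes of hyaluronan metabolism are given as single values, with no test of either as a group. Dlk1, Meg3, Rian and Mirg, neighbours on chromosome 12, were expressed in NIH-3T3 and had means under 1 FPKM in both MLg groups. With SHHN, Meg3 fell in NIH-3T3 from 485 ± 31.5 to 192 ± 15.5 FPKM (SD, n = 3; log2 fold change −1.34, adjusted p = 5.43e-07) and Mirg by 0.87 (adjusted p = 0.00266), while Rian (−0.51, adjusted p = 0.0502) and Dlk1 (−0.39, adjusted p = 0.152) did not pass. On chromosome 6, Sgce had 55.2 ± 0.144 FPKM in MLg control and 0.0309 in NIH-3T3 control, whereas Casd1 had 24.2 ± 5.95 FPKM in NIH-3T3 control and was listed at 0 in MLg control. The imprinted RNA H19 rose by 0.94 in NIH-3T3 (adjusted p = 0.0014) and by 1.76 in MLg (adjusted p = 8.53e-06). Cd44, the receptor of hyaluronan, rose by 1.09 in NIH-3T3 and 2.28 in MLg, a difference of −1.18 (SE 0.24, adjusted p = 0.00599), beside the rise of Has2 in MLg (4.92) and the fall of Cemip in both lines (−3.05 and −2.48). Cyp26b1, which degrades retinoic acid, rose by 2.04 and 1.63.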
